A study of Arabidopsis thaliana with 4 samples.

How the data were processed

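The series holds 4 RNA sequencing libraries of Arabidopsis thaliana Col-0, 1 each of roots, leaves, flowers and siliques. Per the labels' protocols, total RNA was treated with DNase, libraries were made with the TruSeq RNA v2 kit and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, reads were processed with TopHat and Cufflinks on the TAIR10 build, and versions are not given in the sources used here. Per the file headers, the deposited gene table holds for each locus and library an FPKM, the lower and upper end of an interval around it and a status, and all 16 per-sample columns were read. The confidence level of the authors' intervals and any further scaling between libraries are not given in the sources used here.

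The table lists 34288 loci. Of these, 32778 carry 1 gene code, 823 join several genes and 687 have no gene name. A further locus of a gene that already had one was found 1049 times. Of 33444 different codes, 32663 were found in the reference annotation used for names, classes and neighbours, a TAIR10.1 copy. In a check of 25362 loci, 25210 (99.4%) overlapped the position of the same code there. Positions are those of the table, counted from 1. An interval on the genome was shared by 6834 loci, and strand is not given.

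Loci without a usable status in all 4 libraries (217) were left out of the comparisons, as were loci under an FPKM of 1 in every organ, which left 23477. Differences were taken on log2(FPKM + 1), with FPKM as deposited. For each pair of organs a locus was counted as higher at a log2 ratio of at least 2 (4-fold) when the lower end of its interval lay above the upper end in the other organ. An organ-preferential locus met this against each of the other 3 organs at an FPKM of at least 1. Organ similarity was Spearman's rho across the compared loci. Organ specificity was the tau index on log2(FPKM + 1), set against 10000 random sets of protein-coding loci matched on the highest value in 10 bins. Shares of detected loci carry 95% Wilson intervals, which cover sampling of loci only.

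The 25 gene lists, fixed with the comparisons, the named-gene rule and most alternatives before the data were examined, were photosystems and antenna, carbon fixation, chlorophyll synthesis, root mineral uptake, root hair, endodermis and suberin, root apex and cap, root triterpene clusters, floral organ identity, tapetum and pollen wall, mature pollen and pollen tube, floral terpenes, meiosis, seed storage and oil bodies, seed regulators, seed coat, endosperm, fruit wall and dehiscence, shoot meristem, cell division, small RNA and DNA methylation, circadian clock, heat shock proteins, reference genes and described long noncoding RNAs. They hold 451 entries for 449 genes. Of the entries, 436 had a row of their own, 12 were joined with another gene and 3 were not analysed here. Of those with a row, 13 had no usable status, and 392 entries were compared. Each was found by its locus code. The reference gave the list's symbol for that code in 420 entries, 5 were entered by code, 20 symbols were not found and 6 belonged to another locus in the reference (EXL1, EXL5, TPS11, CRU2, OLEO4 and TIP41), which were kept by code. No entry was dropped (0). A list's median was placed among 10000 random lists matched on mean log2(FPKM + 1) in 10 bins, for 6 contrasts (each organ against the mean of the other 3, and both matched pairs), 150 percentiles in all. A list of at least 5 compared members stands apart outside the central 95%, as about 5% of lists of independently drawn genes would. Genes that share a function can vary together, so this rate need not hold for the lists used here. The design counted members at 2-fold with separate intervals. The counts without intervals that the results give were added after seeing the data, because the intervals left few members to count.

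Named loci follow a rule fixed beforehand. It takes the 8 largest ratios per direction in each matched pair, and per organ the 8 organ-preferential protein-coding and 3 noncoding loci with the largest ratios and the 3 highest values. For each list it takes up to 4 members with the largest ratios along the list's median and up to 2 against it, and any described noncoding RNA. The same rule without the interval condition was added after seeing the data. Of the loci it takes, 2 are not reported here. Loci outside it are said to be chosen after their values were seen.

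Read totals are not given in the sources used here. From loci whose upper end is 3 times their FPKM, taken as 1 fragment, an FPKM of 1 corresponds to about 169 fragments per kilobase in roots, 165 in leaves, 169 in flowers and 164 in siliques, and these 1-fragment steps differed between organs by ratios of 0.969 to 1.03. Lower ends above 0 were found for 9.36% of loci in roots, 8.15% in leaves, 10.1% in flowers and 8.63% in siliques. The rules were tested on simulated data made from the table. With separate intervals, 18 of 200 loci raised 8-fold and 31 of 200 raised 32-fold were found in roots against leaves, and 16 and 31 in flowers against siliques. Without intervals all 200 were found. Loci raised 2-fold, below the threshold, were not counted under either rule, and 0 unchanged loci were called. The simulated second library was a copy of the first with random noise far below the threshold. The outcomes without intervals, and the lack of calls among unchanged loci, were therefore fixed by the simulation. They do not show how often unchanged loci are called between real libraries. Of simulated lists of 15 genes drawn at random, 4% stood apart unshifted, 73% at a shift of 0.5 and 100% at 1.

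Alternatives covered the pseudocount (0.1 and 5 FPKM), the log2 threshold, the interval condition, median-of-ratios scaling over the 4 libraries (factors 1.13, 0.808, 1.16 and 0.955 for roots, leaves, flowers and siliques), filters on low values, locus length and status, 20 bins, the mean in place of the median, linear tau and matching on the mean. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used, with random seed 1.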

Results

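RNA was sequenced from 4 organs of Arabidopsis thaliana, the thale cress, in the laboratory accession Col-0, in a series whose title names long noncoding RNAs. Roots and leaves came from plants aged 2 weeks on MS plates, and the growth protocol describes the leaf material as the aerial part of the plant. Flowers and siliques, the pods that hold the developing seeds, came from plants aged 5 weeks in soil. All plants grew in long days at 22 °C. Each organ was represented by 1 library. No value therefore has a replicate error, no difference could be set against a spread between replicates, and no p-value is given. The age and the medium were shared within 2 of the 6 pairs of organs, roots with leaves and flowers with siliques. In the other 4 pairs the organ changed together with both.

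The authors' table gave a value in FPKM, fragments per kilobase of transcript scaled to the sequencing depth, for 34288 loci, of which 34071 had a usable status in all 4 libraries. At an FPKM of at least 1, 19193 of these loci were detected in roots, 17863 in leaves, 20481 in flowers and 19499 in siliques. The 23477 loci detected in at least 1 organ were compared. A status marking too much data left 3 loci listed at 0 in roots, 16 in leaves and 13 in siliques, among them 10 antenna genes in leaves, so the ranking of the highest values leaves these out. The highest listed values in roots were those of TCTP (AT3G16640), a translationally controlled protein, at 4439.6 FPKM, the glycine-rich GRP9 (AT2G05440) at 2227 and AT1G07590 at 2177. In leaves the photosystem subunits PSAO (AT1G08380) and PSBR (AT1G79040) stood at 4266 and 4193 FPKM and the Rubisco small subunit RBCS3B (AT5G38410) at 4099. In flowers the Rubisco small subunit RBCS1A (AT1G67090) reached 4855 FPKM, although it was listed at 0 in leaves and siliques with a status that kept it out of the comparisons. The lipid transfer protein LP1 (AT2G38540) followed at 3468 and TCTP at 2901. In siliques the lipid transfer proteins LTP6 (AT3G08770) and LTP4 (AT5G59310) stood at 10042 and 5104 FPKM and RBCS3B at 5068. The 10 highest usable loci held 3.24% of the FPKM sum in roots, 5.55% in leaves, 3.36% in flowers and 6.21% in siliques. Chloroplast-encoded loci held 0.0162%, 0.201%, 0.195% and 0.22%, in the same order.

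Flowers and siliques were the most alike of the 6 pairs, with a Spearman's rho of 0.825 across the compared loci. Leaves followed with siliques at 0.797 and with flowers at 0.793, although those organs differed from leaves in age and medium. Roots stood apart from the other organs, at 0.721 with leaves, 0.607 with siliques and 0.599 with flowers. Without the filter, loci under an FPKM of 1 in every organ enter, and rho was higher in all 6 pairs. Roots with leaves then reached 0.875, close to leaves with flowers at 0.878 and with siliques at 0.881. Roots with flowers and with siliques stayed the lowest, at 0.797 and 0.800. These correlations run across genes, which are not independent replicates.

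Gene lists for 25 functions and tissues were fixed before the data were examined. For each list the median over its members of the difference in log2(FPKM + 1) was taken, and its percentile was found among 10000 random lists of the same size matched on mean expression, as a description of these libraries. A list is said to stand apart when it lies outside the central 95% of these random lists. Members are counted here at a ratio of at least 2-fold without the interval condition described below, a count added after seeing the data. With that condition, as designed, 6 entries over all lists were higher in roots and 3 in leaves, and 10 in flowers and 3 in siliques. All differences are on the log2(FPKM + 1) scale, which understates those of low genes, and are called log2 ratios.

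**Figure D1:**
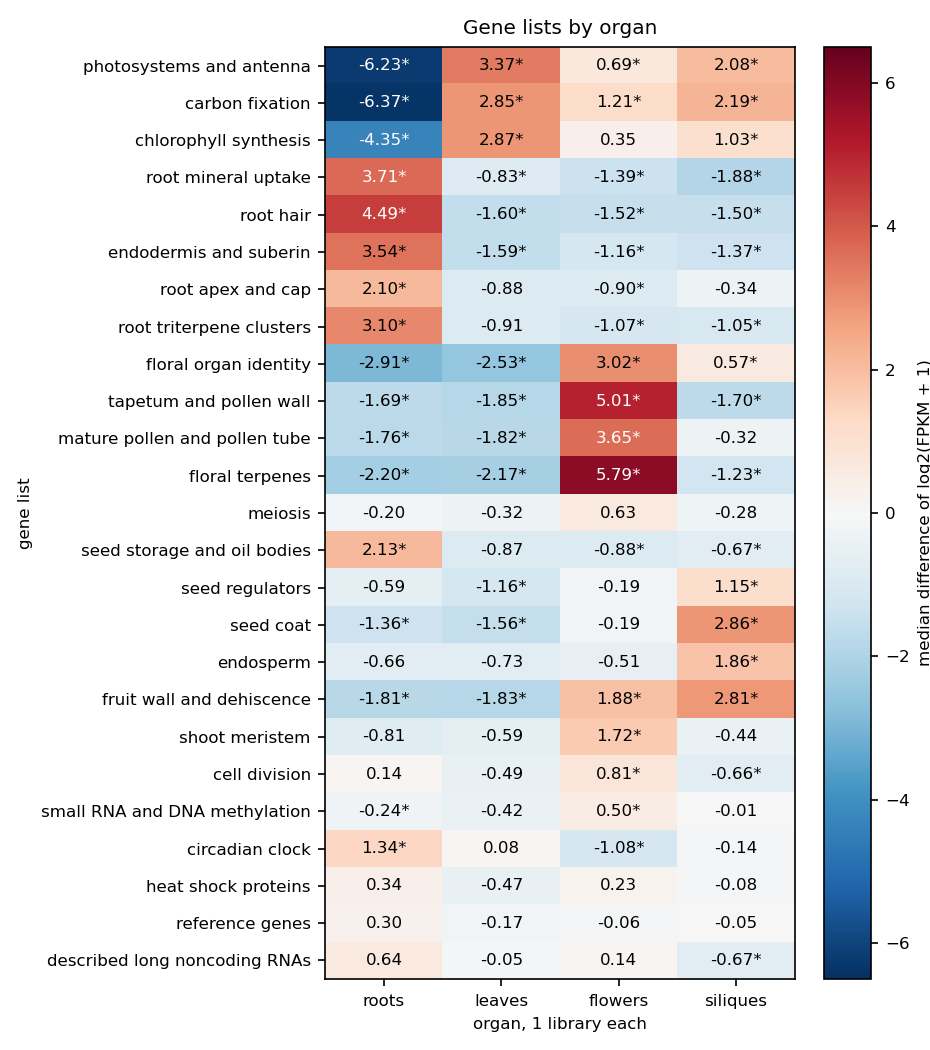
Median over the members of each gene list (vertical axis) of log2(FPKM + 1) in 1 organ minus the mean of the other 3, for roots, leaves, flowers and siliques (horizontal axis, 1 library each), with an asterisk where the list stood apart from matched random lists. The 3 photosynthesis lists lay between -6.37 and -4.35 in roots, and the floral terpene and tapetum lists at 5.79 and 5.01 in flowers.

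Roots against leaves compared the roots and the aerial part of seedlings of the same age on the same medium. Genes of photosynthesis were far lower in roots. All 26 of the 26 compared genes of the photosystems and their antennae were at least 2-fold lower, with a median log2 ratio of -7.24 (percentile 0). The antenna proteins LHCB2.1 (AT2G05100) and LHCB2.2 (AT2G05070) stood at 12.4 and 10.1 FPKM in roots and 3734 and 3065 in leaves. The photosystem I subunits PSAH2 (AT1G52230) and PSAE1 (AT4G28750) went from 1555 and 1713 FPKM in leaves to 5.01 and 6.84 in roots. A further 11 members of that list, 10 antenna genes and PSBO1 (AT5G66570), had no usable status, all of them listed at 0 in leaves. All 12 compared carbon fixation genes were lower in roots (median -6.96, percentile 0), led by the Rubisco small subunits RBCS2B (AT5G38420) at -9.08 and RBCS3B at -9.05, RBCS1B (AT5G38430) at -8.48, and phosphoribulokinase, PRK (AT1G32060), at -7.52. All 7 genes of chlorophyll synthesis were lower too (median -5.52, percentile 0.01). They included the magnesium chelatase subunit GUN5 (AT5G13630) at -6.34, the protochlorophyllide reductases PORB (AT4G27440) at -6.27 and PORC (AT1G03630) at -5.52, and GLK1 (AT2G20570), a transcription factor of chloroplast development also called GPRI1, at -6.13.

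Genes of root functions were higher in roots. Of the 17 compared genes of mineral uptake, 16 were at least 2-fold higher (median 3.49, percentile 100). The iron transporter IRT1 (AT4G19690) stood at 374 FPKM in roots and 0.375 in leaves, and its partner FRO2 (AT1G01580), the ferric chelate reductase, at 141 and 0.546. The ammonium transporter AMT1;3 (AT3G24300) was at 63.0 and 0.714 FPKM, and the phosphate transporter PHT1;1 (AT5G43350), which shares sequence with a near-identical neighbour, at 117 and 2.76. All 19 root hair genes were higher in roots (median 4.48, percentile 100), with the peroxidase PRX44 (AT4G26010) at 79.7 FPKM against 0.201, the cell wall proteins PRP3 (AT3G62680) and AGP3 (AT4G40090) at 73.5 and 71.1 against 0.14 and 0.141, and XTH14 (AT4G25820), a xyloglucan endotransglucosylase, at 62.1 against 0.0388. In the list of the endodermis and suberin, 16 of 18 genes were higher (median 3.92, percentile 100). The Casparian strip proteins CASP1 (AT2G36100) and CASP2 (AT3G11550) had log2 ratios of 6.58 and 5.35, and the peroxidase PER64 (AT5G42180) of 5.71.

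The root apex and cap genes had lower values and were also higher in roots, 9 of 10 (median 2.29, percentile 99.98). They included the stem cell regulators PLT1 (AT3G20840) at 5.98 FPKM and PLT3 (AT5G10510) at 21.0 and the root cap factors SMB (AT1G79580) at 5.62 and BRN1 (AT1G33280) at 5.67. Only the receptor kinase ACR4 (AT3G59420) in that list went the other way, with 2.48 FPKM in roots and 6.08 in leaves. All 8 compared genes of the root triterpene clusters were higher (median 3.06, percentile 100), among them the triterpene synthase PEN1 (AT4G15340) at 25 FPKM and the thalianol pathway genes THAD (AT5G47990), THAH (AT5G48000) and THAS1 (AT5G48010) at 15, 14.3 and 9.14, against at most 0.384 in leaves. Genes of seed storage and oil bodies were higher in roots at low levels, 14 of 18 (median 2.11, percentile 100). The albumins SESA5 (AT5G54740) and SESA3 (AT4G27160) reached 10.9 and 9.30 FPKM in roots against 0.256 and 0.148 in leaves, and the oleosin OLEO1 (AT4G25140) and the storage protein PAP85 (AT3G22640) 7.27 and 7.33 against 0.0994 and 0.248. The late seed gene M17 (AT2G41260) and the dehydrin RAB18 (AT5G66400) went the other way, at -0.88 and -0.58.

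Core genes of the circadian clock differed between roots and leaves in both directions. Of the 14 genes, 7 were at least 2-fold higher and 5 at least 2-fold lower in roots. The evening genes ELF4 (AT2G40080) and TOC1 (AT5G61380) stood at 84.9 and 81.7 FPKM in roots and 4.55 and 15.3 in leaves, and BOA (AT5G59570) and FKF1 (AT1G68050) were also higher in roots, at 1.92 and 1.87. The morning genes CCA1 (AT2G46830) and LHY (AT1G01060) stood at 1.48 and 1.26 FPKM in roots and 44.0 and 19.7 in leaves. The list's median was 1.01 (percentile 99.4), but its mean of 0.13 lay at percentile 43.4. With separate intervals 2 clock genes were lower in roots and none higher. The labels give no hour of harvest.

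**Figure D2:**
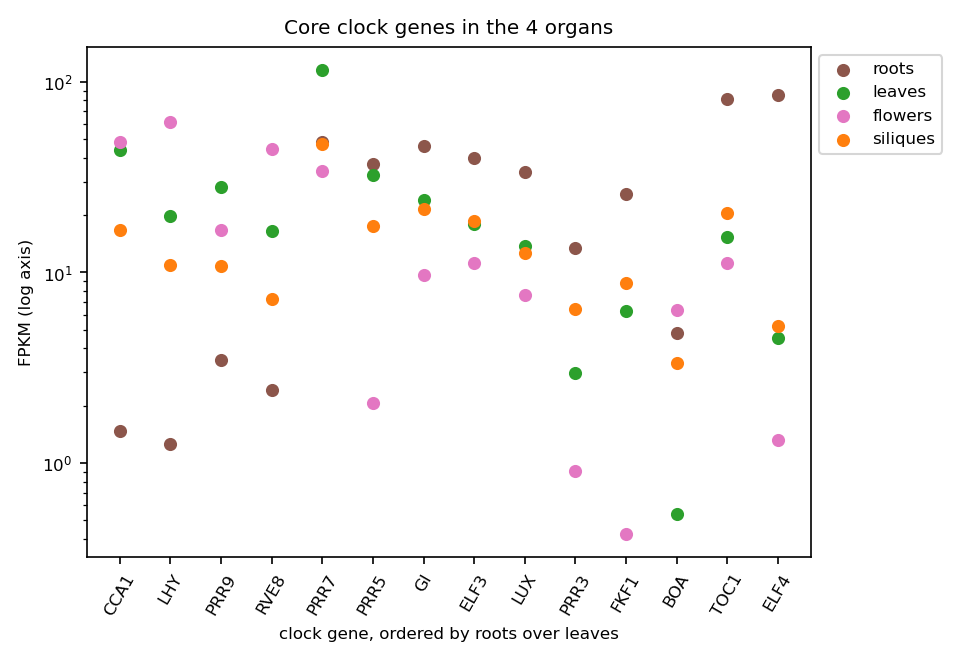
FPKM on a log axis of the 14 core clock genes in roots, leaves, flowers and siliques, 1 point per organ, ordered along the horizontal axis by the log2 ratio of roots over leaves. CCA1 and LHY lay lowest in roots (1.48 and 1.26 FPKM), TOC1 and ELF4 highest there (81.7 and 84.9).

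The other lists had smaller medians between roots and leaves. Floral organ identity genes and shoot meristem genes stood apart as lower in roots at small medians of -0.08 and -0.23 (percentiles 1.97 and 1.67), with 2 of 17 and 1 of 9 genes lower at 2-fold and as many higher. The former no longer stood apart after median-of-ratios scaling (-0.10, percentile 19.7) or with a pseudocount of 5 FPKM, and neither did by the mean over members. Cell division genes had a median of 0.49 (percentile 74.8) and heat shock genes of 0.74 (percentile 79.1). Genes of pollen (0.01), the tapetum (0.00), floral terpenes (0.00), the seed coat (0.00), seed regulators (0.04), the endosperm (0.00) and the fruit wall (0.01) did not stand apart. Apart from the seed coat list (1.85 and 0.55), their median values were at most 0.121 FPKM in roots and 0.293 in leaves. Ratios near 0 at such levels do not show equal expression. Meiosis genes had a median of 0.18 and small RNA genes of 0.20, and the described long noncoding RNAs of 0.27 (percentile 42.3). Genes often used as references in quantitative PCR had 0.39 (percentile 42.3), close to the median of all compared loci, which was 0.34 higher in roots. After median-of-ratios scaling the medians of the meiosis, small RNA, fruit wall, reference and long noncoding lists changed sign.

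Counted one by one, a locus was called higher at a log2 ratio of at least 2 with the authors' interval wholly above that of the other organ. By this rule 151 loci were higher in roots and 167 in leaves. The largest ratios in roots were those of AT5G46900, a lipid transfer type protein, with 171 FPKM (authors' interval 52.6 to 289) against 0.106 (0 to 0.37) at chromosome 5, 19039701 to 19040458 (TAIR10), the extensin EXT13 (AT5G35190) with 138 against 0.046, and FRO2. They were followed by the joined locus of AT4G08400 and AT4G08410 (6.5), the cysteine proteinase CEP2 (AT3G48340) (6.13), the joined locus of AT1G51830 and AT1G51840 (5.82) and the arabinogalactan protein AGP14 (AT5G56540) (5.68). The largest in leaves were plastocyanin, PETE1 (AT1G76100), with 269 FPKM (99.2 to 438) against 1.24 (0 to 3.85) at chromosome 1, 28553845 to 28554886, and the subunits PnsL1 (AT2G39470) and PnsB4 (AT1G18730) of the chloroplast NDH complex (-6.42 and -6.34). Next came a locus that joins AT4G13493, AT4G13494 and AT4G13495 (-6.33), the TIR-NBS gene RLM3 (AT4G16990) (-6.26), the photorespiratory phosphatase PGLP1 (AT5G36700) (-6.18) and AT5G36790, its near-identical copy (-6.19), whose reads cannot be told apart, and GLK1.

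Without the interval condition, 2135 loci were higher in roots and 1742 in leaves. Under this rule, added after seeing the data, the extensins AT3G28550 and AT1G23720 had the largest ratios in roots, at 847 and 603 FPKM, against at most 0.348 in leaves. The others were the glycine-rich AT2G05510 (8.51), the extensin AT3G54580 (8.45), the glycosyl hydrolase BGLU21 (AT1G66270) (8.16), IRT1, MLP328 (AT2G01520) (7.92) and AT1G19530 (7.91). In leaves the myrosinase TGG1 (AT5G26000) led with 1944 FPKM against 2.26, followed by RBCS2B, RBCS3B and the carbonic anhydrases CA1 (AT3G01500) (-9.04) and CA2 (AT5G14740) (-8.63). The defensin-like AT3G05730 (-8.81), the lipid transfer type AT2G10940 (-8.76) and the antenna protein LHCB2.3 (AT3G27690) (-8.74) completed these. Scaling moved the balance of the calls: 47.5% of those with separate intervals were higher in roots as deposited and 35.5% after median-of-ratios scaling, and without the interval condition 55.1% and 43.7%. At an FPKM of at least 10, between 75% and 77.1% of the intervals in each library reached down to 0. Among protein-coding loci at that level, lower ends above 0 were found in roots for 9.76% with 1 annotated transcript and 49.5% with 3 or more. In leaves these were 9.18% and 46.5%. The counts and loci named with separate intervals may therefore favour genes with several transcripts, a comparison chosen after seeing the data.

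**Figure D3:**
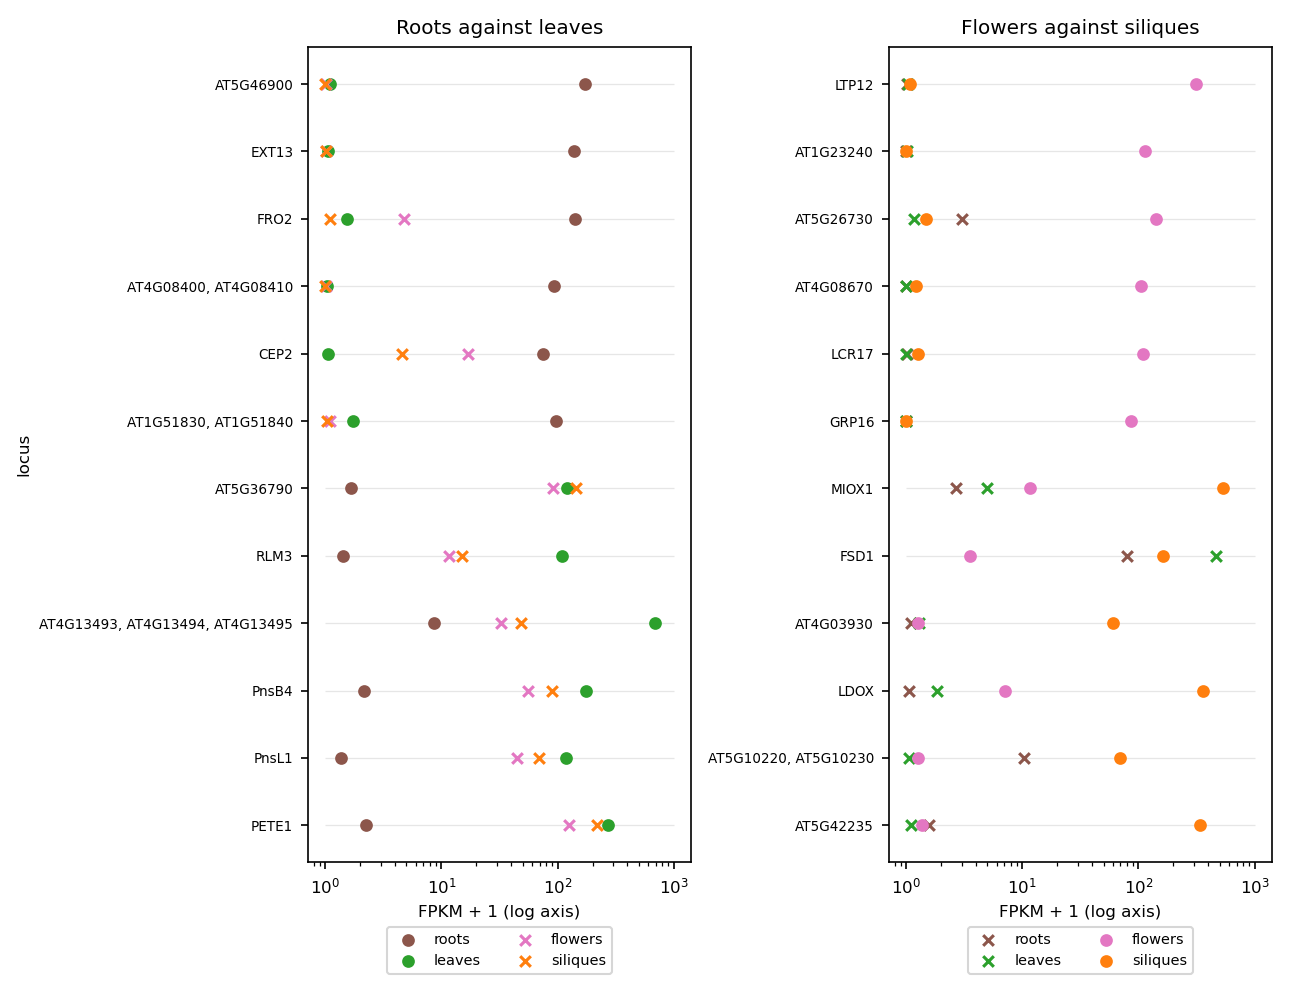
FPKM + 1 on a log axis of the loci with the largest log2 ratios and separate intervals, 6 per direction (vertical axis), for roots against leaves and flowers against siliques, 1 library per organ. Circles are the compared organs and crosses the other organs. PETE1 stood at 1.24 FPKM in roots and 269 in leaves, LTP12 at 315 in flowers and 0.0763 in siliques.

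Flowers against siliques compared flowers with the pods that form from them, on plants of the same age in soil. Genes of male development were far higher in flowers. All 22 compared genes of the tapetum and the pollen wall were at least 2-fold higher (median log2 ratio 5.06, percentile 100). The pollen coat oleosins GRP19 (AT5G07550) and GRP17 (AT5G07530) stood at 815 and 566 FPKM in flowers and 0.0804 and 0.00641 in siliques, the pollen coat lipase EXL4 (AT1G75910) at 318 and 1.28, and the tapetal ATA7 (AT4G28395) at 134 and listed at 0. Of the 39 compared genes of mature pollen and the pollen tube, 37 were higher in flowers (median 3.0, percentile 100). The proton pump AHA6 (AT2G07560) and the pectin methylesterase PPME1 (AT1G69940) had 65.1 and 258 FPKM in flowers and 0.0277 and 3.06 in siliques, and the sugar transporter STP9 (AT1G50310) and the profilin PRF5 (AT2G19770) ratios of 5.40 and 5.04. The tubulin TUB9 (AT4G20890) and GEX1 (AT5G55490), both at -0.16, were the exceptions. All 8 floral terpene genes were higher in flowers (median 4.88, percentile 100), with the cytochrome P450 CYP71B31 (AT3G53300) at 95.1 FPKM against 0.00989, the stamen regulator MYB21 (AT3G27810) at 68.9 against 0.29 and the terpene synthases TPS21 (AT5G23960) and TPS11 (AT5G44630) at 55.9 and 99.6 against 0.68 and 2.26.

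Genes of meristems and division were also higher in flowers. Of 9 shoot meristem genes, 7 were at least 2-fold higher (median 1.66, percentile 99.95), among them the stem cell regulators WUS (AT2G17950) with 9.42 FPKM against 0.018 and STM (AT1G62360) with 41.3 against 10.7. The knotted-like genes KNAT6 (AT1G23380) and KNAT2 (AT1G70510) had ratios of 2.12 and 1.76. Of 28 cell division genes, 15 were higher and none lower at 2-fold (median 1.09, percentile 100). The cyclins CYCA1;1 (AT1G44110), CYCB2;4 (AT1G76310) and CYCA2;3 (AT1G15570) had ratios of 1.83, 1.72 and 1.68, and the Aurora kinase AUR2 (AT2G25880) of 1.74. The described long noncoding RNAs stood apart as higher in flowers (2 of 12 at 2-fold, median 0.71, percentile 98.7) by the median but not by the mean or with a pseudocount of 5 FPKM. Floral organ identity genes did not stand apart (0.54, percentile 97.0), but did as higher in flowers by the mean (1.0) and with a pseudocount of 5 FPKM (0.38).

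Genes of the seed coat and the endosperm were mostly higher in siliques. Of 15 seed coat genes, 10 were at least 2-fold lower in flowers (median -2.75, percentile 0). The anthocyanidin reductase BAN (AT1G61720), which makes the tannins of the seed coat, stood at 10.5 FPKM in flowers and 582 in siliques. The regulator MYB5 (AT3G13540) was at 1.32 and 62.0, the laccase TT10 (AT5G48100) at 0.909 and 36.7, and the transporter TT12 (AT3G59030) at 2.04 and 50.1. Of 14 endosperm genes, 10 were lower in flowers (median -1.69, percentile 0), with the imprinted genes PHE1 (AT1G65330) and FWA (AT4G25530) at 12.3 and 11.4 FPKM in siliques against 0.182 and 0.349, and ZOU (AT1G49770) and PHE2 (AT1G65300) at 6.2 and 6.78. Of 10 seed regulators, 5 were at least 2-fold lower and 2 higher in flowers (median -0.82, percentile 0.33). The embryo regulators LEC1 (AT1G21970) and LEC2 (AT1G28300) stood at 19.4 and 2.07 FPKM in siliques and 0.025 and 0.0829 in flowers, L1L (AT5G47670) and MYB118 (AT3G27785) at 3.31 and 8.10 in siliques, while ABI5 (AT2G36270) and MYB115 (AT5G40360) were higher in flowers (1.44 and 1.95). Of 11 fruit wall genes, 5 were lower and 0 higher (median -0.73, percentile 0.06), with the largest ratios in the lignification factors NST3 (AT1G32770) (-3.16) and NST1 (AT2G46770) (-1.65) and the valve margin genes IND (AT4G00120) (-1.95) and SHP1 (AT3G58780) (-1.92).

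Seed storage and oil body genes, by contrast, were low in both organs, with 3 of 18 lower and 1 higher in flowers at 2-fold (median -0.13, percentile 1.86). The oleosins OLEO2 (AT5G40420), OLEO3 (AT5G51210) and OLEO1 (AT4G25140) were higher in siliques, at 2.23, 10.1 and 1.74 FPKM, and the oleosin OLEO5 (AT3G18570) in flowers, at 4.2. That list did not stand apart by the mean or after scaling. The 3 photosynthesis lists stood apart as lower in flowers, though most of their genes did not reach 2-fold. Those that did were 12 of 26 of the photosystems, 3 of 12 of carbon fixation and 2 of 7 of chlorophyll synthesis (medians -0.99, -0.82 and -0.51, percentiles 0, 0 and 0.87). Clock genes differed here as well. 3 were at least 2-fold higher and 5 lower in flowers (median -0.67, percentile 0), with RVE8 (AT3G09600) and LHY at 2.47 and 2.38 and FKF1, PRR5 (AT5G24470), PRR3 (AT5G60100) and ELF4 at -2.79, -2.59, -1.96 and -1.43. By the mean (-0.34) the clock list did not stand apart. The lists of mineral uptake (0.03), root hairs (0.00), the endodermis (0.03), the root apex (-0.09), root triterpenes (0.00), meiosis (0.50), small RNAs (0.35), heat shock (0.12) and reference genes (0.01) did not stand apart. The last 2 changed sign after scaling. Median values of the root hair, root apex and root triterpene lists were at most 0.0358 FPKM in flowers and 0.342 in siliques. Ratios near 0 at such levels do not show equal expression.

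With separate intervals, 49 loci were higher in flowers and 39 in siliques, and without that condition 1160 and 853. The share higher in flowers was 55.7% with intervals and 57.6% without as deposited, and 50% and 50.3% after median-of-ratios scaling. The 8 largest ratios with intervals in flowers were those of the lipid transfer protein LTP12 (AT3G51590) (315 FPKM against 0.0763, chromosome 3, 19135665 to 19136683), the caleosin AT1G23240 (6.84), the fasciclin-like AT5G26730 (6.59), the lipid transfer type AT4G08670 (6.43), LCR17 (AT4G11760) (6.43), the pollen coat protein GRP16 (AT5G07540) (6.42), ACOS5 (AT1G62940) of sporopollenin synthesis (6.11) and AT1G23570 (5.98). In siliques they were those of AT5G42235 (335 FPKM against 0.364, chromosome 5, 16886847 to 16887570), the joined locus of AT5G10220 and AT5G10230 (-5.78) and LDOX (AT4G22880), an enzyme of anthocyanin and tannin synthesis (355 against 6.11). The pectin methylesterase inhibitor type AT4G03930 (-5.60), the iron superoxide dismutase FSD1 (AT4G25100) (-5.53), the inositol oxygenase MIOX1 (AT1G14520) (-5.53), the lipid transfer type AT5G09370 (-5.47) and the joined locus of AT1G63055 and AT1G63057 (-5.41) followed.

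Under the rule without intervals, added after seeing the data, GRP19 and GRP17 led in flowers, followed by the lipid transfer type AT1G66850 (8.65), LTP12, the anther genes ATA20 (AT3G15400) (8.06) and ATA27 (AT1G75940) (8.02), the lipase type AT1G20130 (7.69) and AT1G68875 (7.61). In siliques the gibberellin-regulated AT2G30810 led with 715 FPKM against 0.855, followed by the glucanase BG3 (AT3G57240) (-8.56), the neighbouring lipid transfer type genes AT5G38160 (-8.55) and AT5G38170 (-8.32), the proline-rich AT1G31250 (-8.21), the cupin AT5G39130 (-8.17) and AT5G42235. The pectin methylesterase inhibitor type AT1G56100 reached 4175 FPKM in siliques and 18.1 in flowers. The median of all compared loci was 0.19 higher in flowers.

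Each organ was then set against the other 3, where organ, age and medium change together for part of the comparison. Roots had the most organ-preferential loci, 97 with separate intervals and 1345 without, and leaves the fewest, 11 and 164. Flowers had 36 and 856, siliques 30 and 662. In roots all 19 root hair genes, 16 of 17 mineral uptake genes, 15 of 18 of the endodermis and all 8 root triterpene genes were at least 2-fold above the mean of the other organs (medians 4.49, 3.71, 3.54 and 3.10, each at percentile 100). Root apex genes followed (2.1, percentile 99.98). Beside the genes named for roots against leaves, the terpene cyclase type AT5G48110 at 74.9 FPKM, AT5G26290 at 58.0, the transporter ABCG35 (AT1G15210) at 66.7, WRKY65 (AT1G29280) at 143 and AT3G01260 at 44.5 were root-preferential with intervals. Without intervals the peroxidase AT3G01190 at 251 FPKM and MLP329 (AT2G01530) at 620.1 joined them. In roots the seed storage list also stood apart as higher, with 13 of 18 genes at 2-fold (median 2.13, percentile 100), CRU3 (AT4G28520) among them at 5.47 FPKM, and OLEO3 lower (-1.24). Clock genes stood apart as higher in roots by the median (1.34, percentile 100, 8 higher and 4 lower at 2-fold) but not by the mean (0.40).

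The 3 photosynthesis lists had their highest medians in leaves, followed by siliques and flowers. The 26 compared genes of the photosystem list held 9.68% of the FPKM sum in leaves, 4.44% in siliques, 2.33% in flowers and 0.0665% in roots. Their median FPKM was 2518, 1198, 625 and 14.7 in that order. The 11 members without usable status were left out in every organ, not only where they were listed at 0. Among them CAB1 (AT1G29930) reached 2292 FPKM in flowers and CAB2 (AT1G29920) 3945 in siliques, so the shares leave out signal. Roots enter the mean against which the list is set in the other organs. Against that mean its median stood at 3.37 in leaves, 2.08 in siliques and 0.69 in flowers, each at percentile 100, with 26, 26 and 3 of 26 genes higher at 2-fold. Carbon fixation had 2.85, 2.19 and 1.21 (11, 11 and 9 of 12), and chlorophyll synthesis 2.87, 1.03 and 0.35 (7, 4 and 2 of 7), the last of which did not stand apart. The leaf-preferential loci with intervals were led by the growth regulator HBI1 (AT2G18300) at 116 FPKM, AT5G44580 at 154, AT4G13575 at 34.7 and the receptor genes RLP19 (AT2G15080) and CRK21 (AT4G23290) at 33.9 and 30.8. The glycine-rich GRP-3 (AT2G05520) at 903 FPKM, CYP79F1 (AT1G16410) of glucosinolate synthesis at 59.2 and RLM3 followed. Without intervals, the defensin-like AT3G05730 and its neighbour AT3G05727 stood at 496 and 393 FPKM in leaves and at most 0.331 elsewhere. The lipid transfer type genes AT4G22517, AT4G22513 and AT4G22485 stood at 327, 229 and 146 FPKM, with their neighbour AT4G22510 at 107, and the thionin AT1G66100 and AT3G16670 at 251 and 157.

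In flowers, 15 of 17 floral organ identity genes were at least 2-fold above the mean of the other organs (median 3.02, percentile 100), led by PI (AT5G20240) at 241 FPKM, AP1 (AT1G69120) at 77.8, CRC (AT1G69180) at 28 and AP3 (AT3G54340) at 119.8. In siliques 8 of the 17 were at least 2-fold higher (median 0.57, percentile 99.9). The ovule gene STK (AT4G09960) stood at 183 FPKM in siliques and 46.6 in flowers, SHP2 (AT2G42830) at 86.9 and 27.4, and the E-class genes SEP1 (AT5G15800) and SEP2 (AT3G02310) at 112 and 139.5 in siliques, while PI and CRC stood at 2.89 and 0.0332 there. The lists of floral terpenes (5.79), the tapetum (5.01), pollen (3.7), shoot meristems (1.72), fruit walls (1.88) and cell division (0.81) stood apart as higher in flowers, the last 3 with 7 of 9, 7 of 11 and 8 of 28 genes at 2-fold. Small RNA and DNA methylation genes did so more weakly (7 of 28, median 0.50, percentile 99.2), and no longer by the mean. In that list the Argonautes AGO9 (AT5G21150) and AGO5 (AT2G27880) were at 83.6 and 23.6 FPKM in flowers and 53.9 and 34.1 in siliques, and at most 0.175 in roots and leaves, and AGO4 (AT2G27040) and DCL3 (AT3G43920) were at 56.1 and 12.4 in flowers. Meiosis genes did not stand apart in flowers (0.63, percentile 88.7), with DMC1 (AT3G22880) at 13.4 FPKM and HEI10 (AT1G53490) at 9.29. Clock genes stood apart as lower (-1.08, 8 lower and 4 higher), with PRR5 at 2.07 FPKM and FKF1 at 0.425, against LHY at 61.4 and RVE8 at 44.6. Beside genes named for flowers against siliques, the glycine-rich AT1G27710 at 73.4 FPKM was among the 8 with the largest ratios.

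In siliques the seed coat (2.86), fruit wall (2.81) and endosperm (1.86) lists stood apart as higher, each at percentile 100, and the seed regulators (1.15, percentile 99.8, 6 of 10 at 2-fold). The regulators TT2 (AT5G35550) of the seed coat and FUL (AT5G60910) of the fruit wall stood at 28.7 and 54.2 FPKM. The seed storage list stood apart as lower (-0.67, percentile 1.29, 2 of 18 lower and 1 higher at 2-fold), though not by the mean (-0.33), with a pseudocount of 0.1 FPKM (-1.09) or with 20 expression bins. Cell division genes were lower (-0.66, percentile 0), with 12 of 28 at 2-fold, among them CYCB2;1 (AT2G17620) at 0.722 FPKM. The pollen list did not stand apart (-0.32, percentile 19.3), and with a pseudocount of 0.1 FPKM it stood apart as higher (0.45). Among endodermis genes, whose list was lower in siliques (-1.37), PER64 and KCS2 (AT1G04220) went against the median, PER64 at 429 FPKM in siliques and 72.7 in roots and KCS2 with a log2 ratio of 2.53. Silique-preferential loci with intervals included GAMT1 (AT4G26420), a gibberellin methyltransferase, at 56.1 FPKM, the response regulator RR22 (AT3G04280) at 76.2 and RGP4 (AT5G50750) at 69.0. RR22 lies in an interval of 36 loci and CRK21 of leaves in 1 of 11. Other loci named for the organs and lists that share theirs are PnsL1, PnsB4, PSBR, MYB21, RGP4, KCS2, CYCA2;3, STP9, HEI10, PHE2, CASP1, PER64, SHP1, SHP2, SEP1, RVE8, DCL3, TT12, MYB5, MYB115, L1L, OLEO1, PRX44, PLT3, GEX1, TAS1A, TAS1C, AT3G01260, AT1G27710, AT4G13575, AT4G03930, the neighbours AT4G22510, AT4G22513 and AT4G22517, and the joined loci AT4G08400, AT1G51830 and AT5G10220.

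Of the lists with general functions, heat shock genes stood apart in no organ, with medians of 0.34 in roots, -0.47 in leaves, 0.23 in flowers and -0.08 in siliques, of which the last changed sign after scaling. Reference genes stood apart in none either, at 0.30, -0.17, -0.06 and -0.05, with the signs in leaves and siliques changed by scaling. Actin 2, ACT2 (AT3G18780), was at 698 FPKM in roots, 281 in leaves, 166 in flowers and 155 in siliques. Described long noncoding RNAs stood apart as lower in siliques (3 of 12 at 2-fold, median -0.67, percentile 0.35), and not in roots (0.64), leaves (-0.05) or flowers (0.14), where the signs in leaves and flowers changed with scaling and the list then stood apart as higher in leaves (0.34). Cell division genes in roots (0.14) and small RNA genes in siliques (-0.01) also changed sign.

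The other 4 pairs join organs of different age and medium. Roots against flowers gave 154 loci higher in roots and 227 in flowers with separate intervals, and 1952 and 2845 without. Roots against siliques gave 175 and 185 with and 2138 and 2493 without. Leaves against flowers gave 37 loci higher in leaves and 125 in flowers with intervals, and 568 and 1900 without. Leaves against siliques gave 32 and 100 with and 651 and 1660 without. In these pairs organ cannot be told apart from age and medium.

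Long noncoding RNAs, the subject named in the series' title, were set against protein-coding loci by locus class. The class joins the reference's lncRNA, ncRNA and antisense RNA loci. Many of these share their interval with another locus. Since strand is not given, the values of the class may include reads of overlapping loci. 249 of 300 annotated long noncoding loci with usable status were detected in at least 1 organ, which is 83.0% (95% Wilson interval 78.3 to 86.8%), against 84.8% (84.3 to 85.2%) of protein-coding loci. Detected long noncoding loci had a median highest FPKM of 8.10, protein-coding loci of 18.8. Their organ specificity, as the index tau from 0 (even) to 1 (1 organ), had a median of 0.25, against 0.231 in all detected protein-coding loci and 0.321 in protein-coding loci matched on the highest value (percentile 0.22). At an FPKM of at least 5 the median was 0.222 (percentile 58.0) and no longer stood apart. Of the 249, 102 were highest in roots, 90 in flowers, 29 in siliques and 28 in leaves. These are 41.0%, 36.1%, 11.6% and 11.2%, near the 40.0%, 31.2%, 15.3% and 13.6% of detected protein-coding loci. Whether scaling moves this split was not tested.

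Several long noncoding loci met the rule for 1 organ. With separate intervals AT5G06865 (chromosome 5, 2132197 to 2133746, TAIR10) was root-preferential at 109.7 FPKM against at most 14.5 elsewhere. Without intervals, under the rule added after seeing the data, AT5G07322 (chromosome 5, 2313119 to 2313563) and AT3G12502 (chromosome 3, 3962382 to 3964222) stood at 55.9 and 20.8 FPKM in roots and at most 1.39 and 0.696 elsewhere. AT3G22121 (chromosome 3, 7794957 to 7796327) stood at 168 in leaves, but also at 36.6 in flowers and 26.6 in siliques, with a tau of 0.477. AT5G40348 (chromosome 5, 16136581 to 16146792) and AT4G04077 (chromosome 4, 1961139 to 1961892) stood at 55.0 and 59.5 FPKM in flowers and at most 0.166 and 2.83 elsewhere. AT2G19796 (chromosome 2, 8529916 to 8530187) stood at 84.2 in siliques and was listed at 0 in the other organs, and AT2G47895 (chromosome 2, 19610473 to 19613220) at 256 in siliques and 4.11 in flowers. AT5G07322 and AT2G19796 lie alone in their intervals. The others share theirs with other loci, and since the table gives no strand, reads of overlapping loci cannot be told apart.

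Among the described noncoding RNAs, the phosphate starvation RNA AT4 (AT5G03545) stood at 131 FPKM in roots, 21.8 in leaves, 2.27 in flowers and 0.953 in siliques, and its relative IPS1 (AT3G09922) at 0.585, 5.14, 0.0129 and 0.718. ASCO (AT1G67105), which binds splicing factors, was highest in roots at 12.7 FPKM, and APOLO (AT2G34655), a regulator of auxin transport, in flowers at 22.6. GUT15 (AT2G18440) was high in all 4 organs, from 137 FPKM in roots to 195 in flowers. The precursors of trans-acting small RNAs TAS1A (AT2G27400), TAS1B (AT1G50055), TAS1C (AT2G39675), TAS2 (AT2G39681) and TAS3 (AT3G17185) had 18.1, 6.88, 9.56, 16.6 and 44.6 FPKM in roots and 2.86, 1.97, 5.39, 10.5 and 30.3 in siliques. In leaves they had 15.2, 5.55, 7.75, 17 and 25.7 FPKM and in flowers 5.79, 4.63, 9.23, 23.5 and 34.5. As deposited, TAS2 was highest in flowers and the other 4 in roots. Dividing by the scaling factors, 1.13 for roots, 0.808 for leaves, 1.16 for flowers and 0.955 for siliques, changes most of these ranks. Leaves then come first for TAS1A, TAS1B, TAS1C and, closely ahead of flowers, TAS2. Only TAS3 stays highest in roots. TAS4 (AT3G25795) and ELENA1 (AT4G16355) were low, at most 1.24 and 1.15 FPKM, both in roots. IPS1 and APOLO are annotated as protein-coding in the reference. HID1 and DRIR were not analysed here.

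Loci without a gene name were detected less often than protein-coding loci. Of 675 with usable status, 245 were detected, 36.3% (95% Wilson interval 32.8 to 40.0%), with a median highest FPKM of 2.62. Their median tau of 0.858 compared with 0.561 in matched protein-coding loci (percentile 100), but with 0.873 (percentile 20.5) in loci matched on the mean in place of the highest value. 92 were highest in flowers, 73 in siliques, 51 in roots and 29 in leaves. Of 674 nuclear ones, 251 overlapped no gene of the reference annotation, 128 long noncoding genes only, 156 protein-coding genes and 139 other genes. The organ-preferential ones with the largest ratios, without the interval condition, were XLOC_003532 in roots (19.9 FPKM, chromosome 1, 25119371 to 25120008), XLOC_014124 in flowers (58.8 FPKM, chromosome 2, 1385454 to 1386073) and XLOC_029296 in siliques (24.7 FPKM, chromosome 5, 21357700 to 21358441). In leaves they were XLOC_032981 (8.02 FPKM, chromosome 5, 21142616 to 21144991) and XLOC_008502 (7.29 FPKM, chromosome 1, 17389111 to 17389568), both below the threshold with a pseudocount of 5 FPKM. A run of 5 neighbouring loci on chromosome 3, from 8362589 to 8373116, chosen after its values were seen, overlapped no annotated gene. All 5 were highest in siliques, from 1.23 FPKM in XLOC_018854 to 62.7 in XLOC_021039, and at most 4.15 in flowers.

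**Figure D4:**
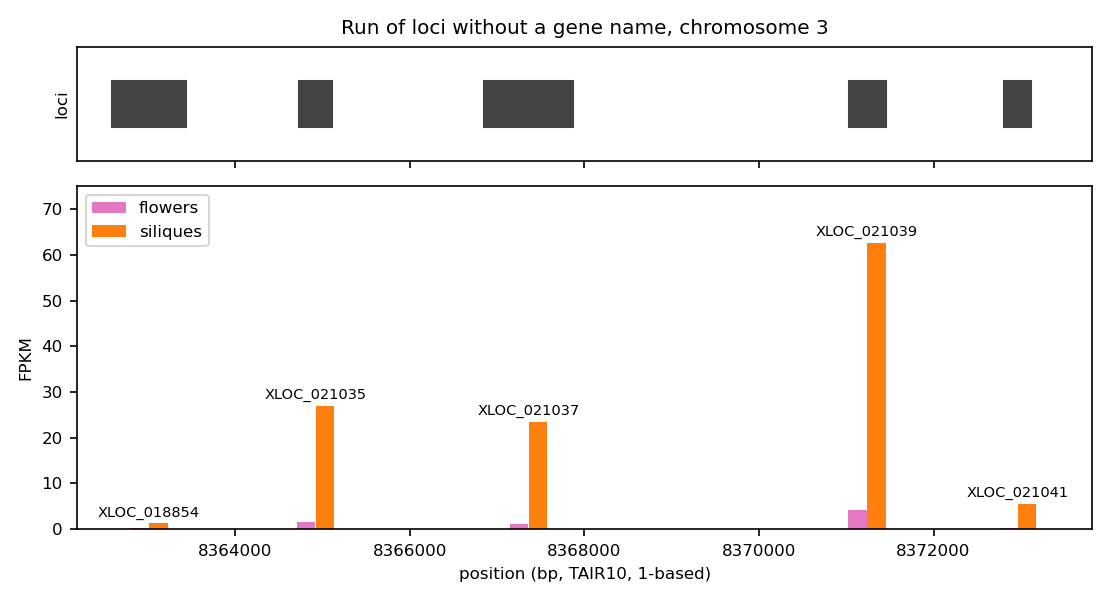
Map of the 5 unnamed loci on chromosome 3 (horizontal axis, position in bp, TAIR10) as boxes, above bars of the FPKM of each locus in flowers and siliques, 1 library each. The silique bars reach from 1.23 to 62.7 FPKM and the flower bars at most 4.15.

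Precursors of microRNAs were detected at 43 of 147 loci (29.3%), and pseudogenes or transposons at 315 of 4692 (6.71%). The median tau of the former was 0.65 (percentile 94.3 among matched protein-coding loci) and of the latter 0.49 (percentile 24.5), and neither stood apart.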

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

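The test of transcript number, the test of intervals at the highest values, the test of embryo regulators and the values on young seeds were chosen only after the result was seen.

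Loci left out for their status still held signal. Of them, 171 reached an FPKM of at least 1 in at least 1 organ. RBCS1A (AT1G67090), a Rubisco small subunit, stood at 4855 FPKM in flowers and was listed at 0 in leaves and siliques. The antenna genes CAB2 (AT1G29920), LHCB3 (AT5G54270) and LHB1B2 (AT2G34420) stood at 3945, 3798 and 3429 FPKM in siliques and were listed at 0 in leaves. The beta-glucosidase PYK10 (AT3G09260) stood at 208 FPKM in leaves and was listed at 0 in roots. These zeros carry a status marking too much data. LHCB3, LHB1B2 and PYK10 share their intervals with another locus.

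Few loci had an interval clear of 0. Among protein-coding loci at an FPKM of at least 10, a lower end above 0 was at least 4.96 times as frequent with 3 or more annotated transcripts as with 1, in each organ, so the authors' interval may depend on transcript number. The other explanation, too few fragments, met the prediction of the test chosen beforehand, since among genes with 1 transcript the share was 4.78 to 5.98 times as high at an FPKM of at least 100 as at 1 to 10. A second test, chosen afterwards, spoke against this as the whole cause, since at least 91.9% of such genes at an FPKM of at least 100 still had a lower end of 0 in each organ. A part for depth stays open, and no biological explanation was tested.

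Seed storage genes were higher in roots than in siliques. Late seed genes outside the fixed list, 10 in all, were higher in roots in 10 of 10, with a median of 1.29 above the mean of the other organs and the highest, LEA76 (AT3G15670), at 5.69 FPKM, so remains of the sown seeds in the root library are a candidate source. The median root FPKM of LEC1, LEC2, FUS3 and ABI3 was 0.0137, which argues against an embryo maturation programme in roots. In siliques the endosperm list stood at 1.86 and the seed storage list at -0.67, but the latter is part of the pattern and did not stand apart by the mean, with 20 bins or with a pseudocount of 0.1 FPKM, so these values decide nothing on the age of the seeds. Seed remains, a root expression of these genes without those regulators and the age of the seeds stay open.

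Core clock genes differed between roots and leaves. Of 10 dawn genes outside the fixed list, 9 were lower in roots, with a median log2 ratio of -2.65. Of 6 dusk genes, 4 were higher, with a median of 1.58, and CHE (AT5G08330) and CAT3 (AT1G20620) were lower. Another phase of the clock in the root library may account for this, through the hour of harvest or the organ. The labels give no hour, so these stay open and untested.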

How the results depend on the processing

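The member counts, the named loci without intervals and the lists with members of any status were chosen after seeing the data, the other alternatives before the data were examined. No paired analysis was possible because each organ had 1 library and the labels pair no plants. Of 1050 list results under alternatives, 1010 kept their call (apart as higher, apart as lower, or not apart), 23 no longer stood apart and 17 newly did. Of 411 results for named loci, 409 kept both, and XLOC_032981 and XLOC_008502 fell under the threshold with a pseudocount of 5 FPKM (1.1 and 1.04). Of 236 counts, shares, correlations and tau medians, 211 stayed within the limits set. These were 1.5 times for counts, 0.05 for correlations and 10% for shares of the FPKM sum. For percents detected the limit was the Wilson interval, and for tau medians the same call. Some could not move: without the filter on low values the counts of loci called higher stay the same, since a 4-fold ratio of FPKM + 1 already needs a value above that filter.

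Without the interval condition, counts rose to 2135 and 1742 for roots against leaves, 1160 and 853 for flowers against siliques, 4797 and 4631 for roots against flowers and siliques, 2468 and 2311 for leaves against flowers and siliques, and 1345, 164, 856 and 662 organ-preferential loci in roots, leaves, flowers and siliques. A condition was removed, so every locus counted with it is among them. The percent detected follows the minimum by construction: 87.3% of long noncoding and 58.4% of unnamed loci at 0.5 FPKM, 55% and 8.74% at 5. The median tau of long noncoding loci at 5 FPKM was 0.222 and no longer stood apart, and that of unnamed loci, 0.858, no longer did when matched on the mean. For both, the cause was not tested. Without the filter on low values rho was 0.875 for roots and leaves, 0.905 for flowers and siliques, 0.797 and 0.800 for roots with flowers and siliques, and 0.878 and 0.881 for leaves with flowers and siliques. The cause was not tested. With loci of any status the 10 highest held 3.83% in flowers, where RBCS1A, CAB1 (AT1G29930) and LHCB3 enter. Scaling moved the median of all compared loci from 0.34 to 0 in roots over leaves, 0.19 to -0.01 in flowers over siliques, 0.14 to -0.03 in roots over siliques, -0.38 to 0 in leaves over flowers and -0.12 to 0.01 in leaves over siliques, and 14 list medians changed sign, 0 of them standing apart as deposited. Depth is known only by inference, and with 1 library per organ no spread is known.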

Other observations

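The counts of pollen genes in siliques, microRNA precursors and unannotated loci were chosen only after the results were seen, as were the loci named for them.

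Over 33 pollen genes at an FPKM of at least 5 in flowers, the median silique value was 7.25% of the flower value. It was 0.144% over 19 tapetum genes and 0.859% over 8 floral terpene genes, and the difference between these lists was not tested. AP3 (AT3G54340) stood at 79.0 FPKM in siliques while its partner PI (AT5G20240) stood at 2.89.

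Among precursors of microRNAs, MIR157a (AT1G66783) stood at 19.2 FPKM in roots, 10.4 in leaves, 0.296 in flowers and 0.0105 in siliques, and MIR156c (AT4G31877) at 2.1, 8.26, 0.463 and 0.424. In the same families, MIR157c (AT3G18217) stood at 0.0466, 12.3, 1.89 and 0.354 FPKM and MIR156a (AT2G25095) at 0.31, 4.29, 0.541 and 0.311. These precursors were thus highest in leaves, and in roots no higher than in flowers or siliques. Organ changes together with age and medium here, so no pattern can be assigned to age. MIR172b (AT5G04275) stood at 4.03 FPKM in flowers, 0.257 in siliques, 0.388 in leaves and 0.137 in roots. All but MIR172b share their intervals with other loci.

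Of 76 compared loci without a gene name that overlap no annotated gene, 40 were highest in siliques, 25 in flowers, 7 in roots and 4 in leaves. A further run of 3 loci without a name, all highest in siliques, lies on chromosome 1 from 21942641 to 21948553, where 2 of them overlap AT1G59723 and AT1G59724.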
